A study of Mus musculus with 4 samples.

How the data were processed

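Chromatin immunoprecipitation with an antibody against IRF2, an interferon regulatory factor that binds DNA, was followed by sequencing (ChIP-seq) in Lgr5-positive stem cells of the mouse small intestine. The cells carried an EGFP-Ires-CreERT2 cassette at the Lgr5 locus. The design text names 5 mice, without saying which of the 4 deposited samples they entered. Per the labels' protocols, cells were fixed in 1% formaldehyde for 15 min, chromatin was sheared by sonication, and 30 ug of chromatin entered each immunoprecipitation. The samples are 2 IRF2 immunoprecipitates and 2 input controls, grouped by the antibody label. The inputs were not analysed here, so enrichment over input could not be computed. The IRF2 libraries are called replicate 1 (0082Takara in its title) and replicate 2 (38693Tokyo in its title), in the order of the sample records. The deposit of replicate 2 numbers them the other way round and calls its own library rep1.

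Per the submitters' processing notes, reads were placed on the mouse build mm10 with BWA 0.7.12 and peaks were called with MACS. The MACS version, its thresholds, any duplicate or region filter and the read depth are not given in the sources used here. Per the file headers, each library was called separately and has a track of peak intervals and a track of summits. The deposited summit track gives each peak a score, a whole number whose unit is not stated. It is called the summit value here, and it is the authors' own value for the peak. It was used to rank, describe, compare or filter peaks within its own list. Across regions found in both lists, the values of the 2 libraries were also correlated. The replicate 2 deposit also held a track called rep2, whose 380 summits and intervals were line for line those of replicate 1. That copy was counted once, as replicate 1. A further track held 562 merged regions of both libraries. Joining the intervals of both lists gave the same number of regions. Most summits (371 of 380 and 226 of 238) lay on a grid of 16 bp.

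Genes were the 21887 protein-coding genes on chromosomes 1 to 19, X and Y of the RefSeq table for GRCm38.p6, the assembly on which mm10 is based. The table gives each gene's start and end without a strand, so a transcription start could not be told from the opposite end. Distances were therefore measured from a peak's midpoint to the nearer of both gene ends, in place of the start-site windows planned. No genome sequence was used. The 5 of 9 planned results that search for the IRF consensus, for its position in the peak, for its relation to the score or for enriched 8-mers were not run. Exons and untranslated regions were not used either.

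Peaks of both lists that overlapped by at least 1 bp were joined into shared regions. Overlap between the lists, and the share of peaks within 1000 bp of a gene end, were tested against 1000 random placements. These kept chromosome and width and lay between the first and last gene of the chromosome. The smallest two-sided p such a test can give is 0.002. Placement at random gene ends, with the same distance and side, was an alternative. The 14 gene lists and the rule for named genes were fixed before the data were examined. So were the tests of overlap, of gene-end share (planned for start sites) and of the gene lists. Their alternative settings were fixed too, apart from those named below as chosen later. The comparisons between shared and unshared peaks and between unshared peaks of the libraries were not in that plan. Nor were the comparison of the highest and lowest peaks, the correlation of summit values and the count of shared regions at list members. Of the members of the lists, 275 different genes matched the table by symbol or unique synonym. Mx1 and Mx2 did not match a protein-coding entry. A gene counted as having a peak when a midpoint lay within 5000 bp of either end, and lists were compared with all other protein-coding genes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 14 lists. Medians were compared with two-sided permutation tests of 100000 resamples. The class comparisons form a family of 7 tests, adjusted together. Shares carry 95% Wilson intervals, which cover counting error only.

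Named items followed a rule. It takes the 15 shared regions with the best mean rank of the summit value, list members near a shared region (at most 10 per list), the 5 highest peaks found in each library alone, and 13 genes named whatever their result. Some items that this rule selects are not reported here. Alternatives were the higher-scored 50% of each list, chromosomes 1 to 19 and X, a reciprocal overlap of 50%, midpoints within 500 bp, merging within 500 bp, other windows, ends of all annotated genes, assignment to the nearest gene, and either library alone. Further alternatives were chosen after seeing the data and are named as such. The overlap, gene-end and gene-list tests were tried on simulated data, and the other tests were not. With 50 of 238 replicate 2 peaks moved onto replicate 1 peaks, 20 of 20 runs recovered the overlap. With 60 peaks moved onto gene ends, 20 of 20 runs recovered the excess. With 6 members of a random list of 20 genes given a region, 20 of 20 runs called that list, and 0 of 280 random lists passed. Those lists held genes drawn at random, so they do not cover lists whose members lie in clusters. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

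Nothing in the labels says whether the libraries came from separate animals. The tests below compare places in the genome, and no test treats the 2 libraries as a sample of animals, since their spread may be technical.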

Results

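The series asked where IRF2 binds in intestinal stem cells. The authors called 380 peaks in IRF2 replicate 1 and 238 in IRF2 replicate 2. The median peak width was 525 bp (interquartile range 385 to 774) in replicate 1 and 545 bp (462 to 646) in replicate 2. Summit values ran from 13 to 169 in replicate 1, with a median of 22.5, and from 10 to 80 in replicate 2, with a median of 14. Read depth is unknown for both, so a site missing from a list was not called there, and binding below the calling threshold is not excluded.

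Both libraries had IRF2 peaks at genes of MHC class I antigen presentation and at a set of sites far from gene ends. The highest-ranked shared region next to a gene end lay at Parp12, an interferon-inducible ADP-ribosyltransferase (chromosome 6, 39117412 to 39118821, mm10). Its midpoint was 232 bp inside the high-coordinate end of the gene, and its summit values were 131 in replicate 1 and 48 in replicate 2. Next among gene-end regions came Rbck1, a subunit of the linear ubiquitin ligase complex (summit values 88 and 31), Erap1, which trims peptides for MHC class I (82 and 25), Nmi, an interferon-inducible protein (84 and 23), Tapbp, which encodes tapasin (71 and 29), and Nub1 (74 and 21). A region 2103 bp inside Tasor2 (47 and 27) was also among the 15 best. The remaining 8 of the 15 best-ranked regions lay farther than 5000 bp from any protein-coding gene end. These included the top region, 19 kb from Bmp8b on chromosome 4 (123083799 to 123086846, summit values 169 and 42), and regions inside Map4 (138 and 31), Erbb4 (89 and 22) and Msi2 (49 and 22). The others were nearest to Rnf225 at 6.26 kb (99 and 28), Mlxip at 6.81 kb (121 and 21), Hes1 at 32.8 kb (80 and 21) and Nxph1 at 477 kb (82 and 18).

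The lists overlapped at 53 regions. Of the replicate 1 peaks, 55 of 380 (14.5%, 95% Wilson interval 11.3 to 18.4) overlapped a replicate 2 peak. Of the replicate 2 peaks, 54 of 238 (22.7%, interval 17.8 to 28.4) overlapped a replicate 1 peak. Random placement gave a mean of 0.051 and 0.056 peaks and never more than 2 (two-sided permutation of peak positions, p = 0.002 for each, the smallest it can give). Placement at random gene ends gave at most 3 overlapping peaks, again with p = 0.002 in the permutation. When each peak had to cover 50% of the other, 35 peaks per list were shared, and the regions at Bmp8b, Parp12, Erbb4 and Mlxip were not among them. Shared peaks were the higher ones within each list. The median summit value was 57 for shared and 21 for unshared replicate 1 peaks (two-sided permutation test, adjusted p = 3.5e-05), and 16.5 against 14 in replicate 2 (adjusted p = 5.6e-05). Shared peaks were also wider, with medians of 995 against 487 bp in replicate 1 and 659 against 522.5 bp in replicate 2 (permutation tests, adjusted p = 3.5e-05 for each). Among the 95 highest replicate 1 peaks, 42 (44.2%, interval 34.6 to 54.2) were shared, against 4 (4.21%, 1.65 to 10.3) of the 95 lowest (odds ratio 18.03, Fisher's exact test, p = 3.65e-11). In replicate 2 the counts were 27 of the 60 highest (45%, 33.1 to 57.5) and 7 of the 59 lowest (11.9%, 5.87 to 22.5; odds ratio 6.08, Fisher's exact test, p = 8.53e-05). Across the 53 shared regions, summit values of the libraries were correlated (Pearson r of log2 values = 0.52, permutation p = 2e-05, and Spearman rho = 0.48, permutation p = 0.00026). Without the 2 regions farthest from the median replicate 1 value, r was 0.43. These are correlations across regions, which are not independent replicates.

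**Figure D1:**
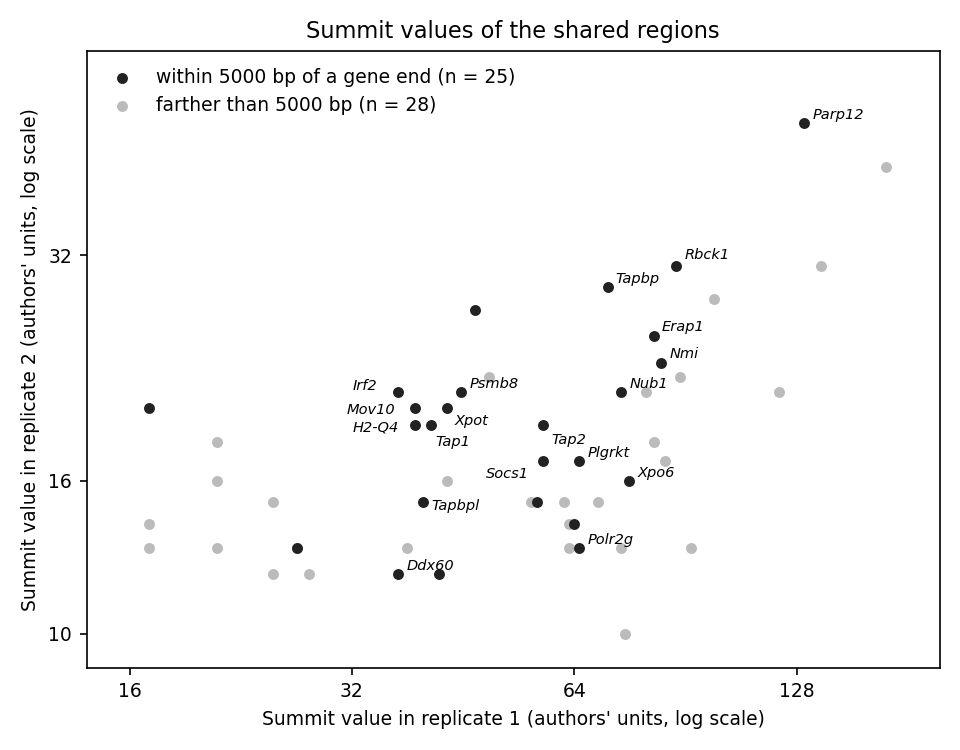
Summit values (the authors' units, log axes) of the 53 shared regions in replicate 1 (x) and replicate 2 (y); each point is a region, black within 5000 bp of a protein-coding gene end (25 regions) and grey farther away (28 regions), with the nearest gene named for regions within 1000 bp. Parp12, at 131 and 48, is the highest gene-end region, and grey points lie among the highest values as well.

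Peaks of both libraries were concentrated at gene ends. In replicate 1, 88 of 380 midpoints (23.2%, interval 19.2 to 27.7) lay within 1000 bp of a protein-coding gene end, against 3.08% under permuted positions (permutation p = 0.002). In replicate 2 the share was 104 of 238 (43.7%, 37.5 to 50.05), against 3.12% (permutation p = 0.002). Among peaks found in 1 library alone, 85 of 184 (46.2%) in replicate 2 and 68 of 325 (20.9%) in replicate 1 were at a gene end (odds ratio 3.24, Fisher's exact test, adjusted p = 2.78e-08). This test counts adjacent calls as separate sites. Merging within 500 bp left 346 peaks in replicate 1 and 235 in replicate 2, and the comparison was not run on merged peaks. Some unshared replicate 1 peaks lay beside a shared region, such as that at 30033013 to 30034254 near Hes1. Gene-end peaks were also commoner among shared than unshared replicate 1 peaks (20 of 55, 36.4%, against 68 of 325; adjusted p = 0.0182, Fisher's exact test). In replicate 2, 19 of 54 shared peaks (35.2%) were at a gene end, which was not distinguishable from its unshared peaks (85 of 184; Fisher's exact test, adjusted p = 0.163). Of the 53 shared regions, 19 lay within 1000 bp of a gene end and 28 lay more than 5000 bp away, 12 of those inside a gene.

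**Figure D2:**
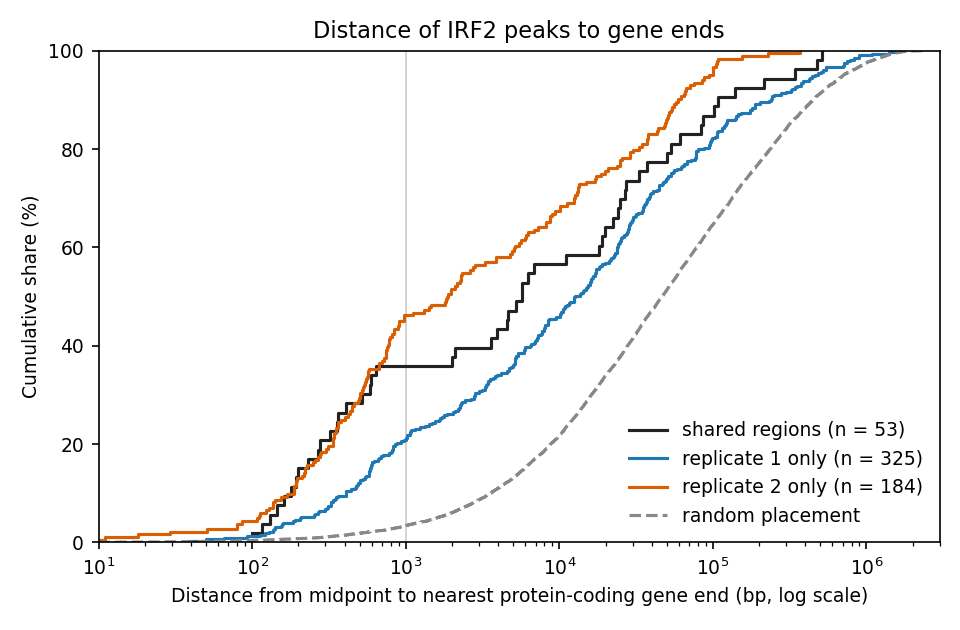
Cumulative share (%) of peak midpoints by distance to the nearest protein-coding gene end (bp, log axis) for shared regions, peaks of each library alone and 20 random placements of both lists; the grey line marks 1000 bp. At 1000 bp the curves stand at 46.2% for replicate 2 alone, 35.8% for shared regions and 20.9% for replicate 1 alone.

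MHC class I antigen presentation was the gene list with the most members at shared regions. A shared region lay within 5000 bp of 8 of its 20 members (40%), against 28 of 21867 other genes (odds ratio 520, Fisher's exact test, adjusted p = 4.04e-17). The 8 genes were Tap1 and Tap2, which form the peptide transporter of the endoplasmic reticulum, Psmb8 and Psmb9, subunits of the immunoproteasome, Tapbp, its homologue Tapbpl, Erap1 and the class I gene H2-Q4. Each of the 8 genes had the midpoint of a shared region within 517 bp of an end. In the cluster on chromosome 17, a region (34186588 to 34188323) spanned the facing ends of Psmb9 and Tap1, with summit values of 41 in replicate 1 and 19 in replicate 2. Another (34197930 to 34199180) covered the low-coordinate end of Psmb8 (45 and 21), and another (34204245 to 34205068) that of Tap2 (58 and 19). H2-Q4 had a region at 35379459 to 35380418 (39 and 19), and Tapbpl one on chromosome 6 at 125231147 to 125232032 (40 and 15). Since neighbours can share a region, regions were also counted. Of the 53 shared regions, 7 were within 5000 bp of a member, against a mean of 0.057 and at most 1 with regions placed at random gene ends (permutation p = 0.002). Among genes outside chromosome 17, an alternative chosen after seeing the data, 2 of 10 members had a shared region (Erap1 and Tapbpl, adjusted p = 0.00109, Fisher's exact test). Taken by itself, replicate 2 had a peak at the same 8 members (Fisher's exact test, adjusted p = 2.42e-11). Replicate 1 by itself had a peak at 14 of 20 (Fisher's exact test, adjusted p = 1.23e-24), the added ones being H2-D1, H2-K1, H2-T22, Psmb10, Psme1 and Psme2. B2m, the class I light chain, and Nlrc5, the class I transactivator, had no peak within 5000 bp in either library. The H2 genes form a multigene family, and how reads were divided among them is not given in the sources used here.

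**Figure D3:**
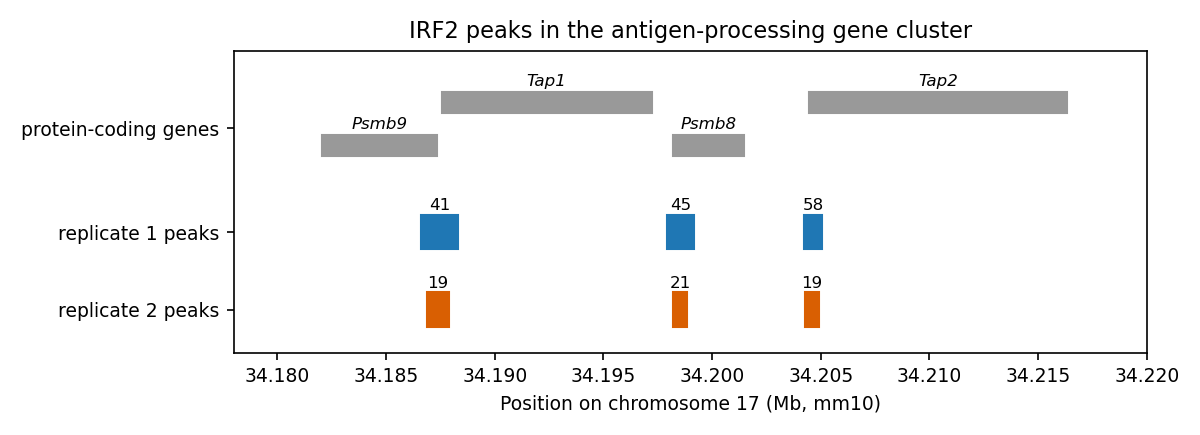
Map of chromosome 17 from 34.178 to 34.22 Mb (mm10) with protein-coding genes in grey and peak intervals of replicate 1 (blue) and replicate 2 (orange), drawn to scale with the summit value above each. Both libraries have 3 peaks in this window, at the facing ends of Psmb9 and Tap1 and at the low-coordinate ends of Psmb8 and Tap2.

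Among 49 interferon-stimulated genes, Nmi was the single one with a shared region within 5000 bp (adjusted p = 0.362, Fisher's exact test). In replicate 1, 8 of 49 (16.3%) had a peak (odds ratio 25.5, Fisher's exact test, adjusted p = 3.25e-08). Among them were Ifih1, an RNA sensor (summit value 31, midpoint 137 bp from an end), Dtx3l and its neighbour Parp9, which share a peak (44), Herc6, an enzyme of ISG15 conjugation (33, 205 bp), Ifi35 (24, 185 bp), the GTPase Gbp2 (21, 159 bp) and Nmi. In replicate 2, 2 of 49 had a peak, Nmi and Cmpk2 (13, 218 bp; Fisher's exact test, adjusted p = 0.414). The difference between the libraries was not tested for this list by itself.

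Irf2 itself had a peak in both libraries, at its low-coordinate end (chromosome 8, 46739085 to 46740693, midpoint 144 bp from the end, summit values 37 and 21). It was the single member of the 12-gene IRF family list with a peak within 5000 bp (Fisher's exact test, adjusted p = 0.137), and its peaks fell short of a reciprocal overlap of 50%, a setting chosen for the gene lists after seeing the data. Irf1, Irf7, Irf9 and Stat2 had none. The nearest replicate 1 peak was 13.3 kb from Irf9, where it is the peak at Psme2, and 81 kb from Irf1.

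Lgr5, the marker used to identify these cells, and the stem cell genes Olfm4 and Ascl2 had no peak within 5000 bp in either library. Neither had Atoh1, which specifies secretory cells, or Gsdmd, the pore-forming protein of pyroptosis. None of 19 stem cell genes, 23 secretory lineage genes, 17 absorptive enterocyte genes, 19 Notch and Wnt pathway genes, 23 cell death genes or 9 MHC class II genes had a shared region within 5000 bp. With 36 of 21887 genes near a shared region, 0.0148 to 0.0378 members per list would be near one by chance, so a count of 0 does not set these lists apart from other genes. In replicate 1, peaks lay 252 and 831 bp from an end of Bak1, a mediator of apoptosis (summit values 20 and 23), and a peak lay 2319 bp from an end of Tcf7l2, a Wnt effector (14). Markers of other cell types (19 lymphocyte, 15 myeloid and 13 mesenchymal or endothelial genes) had 0 members with a peak in either library, where 0.103 to 0.153 per list and library would by chance. The proliferation and ribosomal protein lists had 0 members at shared regions. In replicate 1 each had 2 of 20 (adjusted p = 0.038 for both, Fisher's exact test), namely Mcm6 and Ccnb1, and Rpl18 and Rpl27. The peak lay 363 bp from an end of Ccnb1 (summit value 16), 3125 bp from Mcm6 (16), 1344 bp from Rpl18 (18) and 3001 bp from Rpl27 (24). The Rpl27 peak is the one at Ifi35, and the Rpl18 peak is nearer to Fam83e, at 1008 bp.

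**Figure D4:**
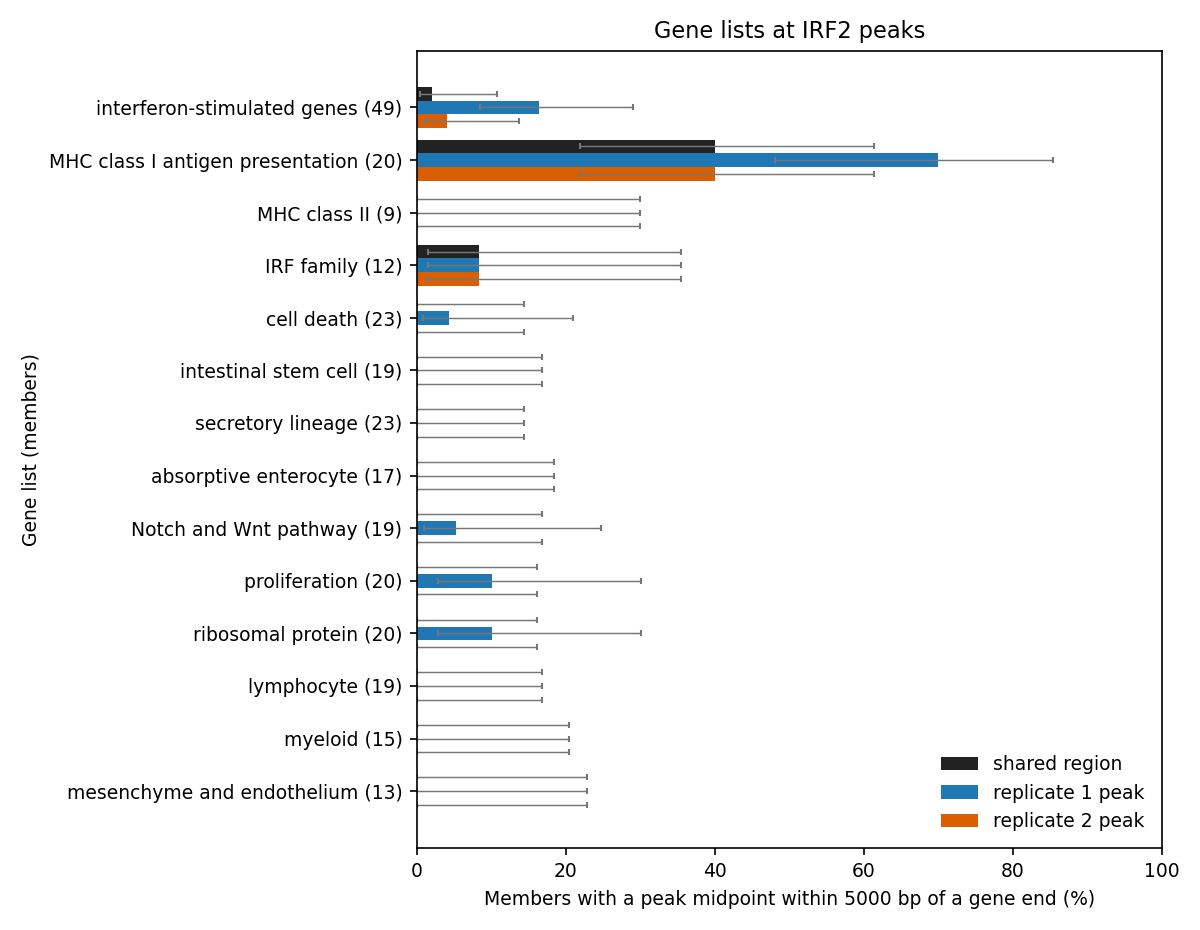
Share (%) of each list's protein-coding members with a peak midpoint within 5000 bp of a gene end, for shared regions (black), replicate 1 peaks (blue) and replicate 2 peaks (orange), with 95% Wilson intervals as bars. MHC class I antigen presentation reaches 40% at shared regions, 70% in replicate 1 and 40% in replicate 2, and interferon-stimulated genes 16.3% in replicate 1.

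The highest peaks found in a single library lay away from the genes of the lists. In replicate 1 they were 243 kb from Tox (chromosome 4, summit value 64), 10.8 kb from Larp1 (61), inside Mme at 29.3 kb from its nearer end (61), 421 kb from Nuf2 (59) and 2.84 kb from Aspg (58, a value tied with the sixth). In replicate 2 they were 368 kb from Arid1b (chromosome 17, summit value 80, the highest of the library), 12.5 kb from Tmem267 (56), 18.6 kb from Cspg5 (41) and inside Scrt2 at 2.08 kb from its nearer end (26).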

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

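The overlap between the lists, the concentration at gene ends, the difference in gene-end share between peaks of replicate 2 and replicate 1 alone, the higher summit values of shared peaks and the excess of MHC class I antigen presentation genes kept their direction and stayed past the threshold under each alternative run. For the alternatives of the class and summit-value comparisons, for overlaps split by distance to genes, and for gene lists with a reciprocal overlap of 50% or without chromosome 17, the settings were chosen after seeing the data. With a reciprocal overlap of 50%, 9.21% of replicate 1 and 14.7% of replicate 2 peaks were shared, and the regions at Bmp8b, Parp12, Erbb4 and Mlxip were no longer among them, nor was that at Irf2. Keeping the higher-scored 50% left 190 and 119 peaks by construction. The number of genes near a shared region was 36, against 22 with a window of 1000 bp and 73 with 25000 bp. Either library alone gave 174 to 176 genes. The interferon-stimulated list rests on replicate 1: it had 1 member at shared regions, between 2 and 8 members with 1 library left out, and passed the threshold with replicate 1 alone (8 members) and not with replicate 2 alone (2 members). The proliferation and ribosomal protein lists, with 2 members each, also passed with replicate 1 alone. Of the 22 genes named by rule, Irf9 gained a replicate 1 peak with the 25000 bp window, which is the peak 407 bp from an end of Psme2. The intended alternatives that need a genome sequence (repeat content, other motifs and the promoters that hold the IRF consensus) were not run. No paired analysis was possible because the inputs were not analysed here and the 2 IRF2 libraries form 1 group. Without the read depths, what depth limits in the shorter list cannot be stated as a number.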

Other observations

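Some genes outside the lists are given here for their known functions. They were picked after their values were seen, and no group was tested. With a peak in replicate 1 and none in replicate 2 within 5000 bp, there were Irgm1, an interferon-induced GTPase (midpoint 50 bp from a gene end, summit value 28), Shfl, an inhibitor of ribosomal frameshifting (112 bp, 29), Trim26 (338 bp, 38), the cytidine deaminase Apobec3 (411 bp, 20) and Il15ra, the interleukin-15 receptor alpha chain (602 bp, 24). Shared regions also reached Socs1, a suppressor of cytokine signalling (58 in replicate 1 and 17 in replicate 2), Ddx60 (37 and 12), Mov10 (39 and 20), the interval between Tbk1 and Xpot (43 and 20), and an end of Plgrkt (65 and 17, midpoint 192 bp away). The region at Plgrkt also lies inside Cd274, the gene of PD-L1, with its midpoint 4993 bp from the nearer end of Cd274. The replicate 2 peak there was 5120 bp from that end, outside the 5000 bp window.

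Genes were also grouped by the first 3 characters of their symbols, an exploratory test chosen after the peak lists were seen, over 530 families of at least 8 genes. Among genes with a replicate 1 peak alone, the H2 family had 5 of 38 members, H2-D1, H2-K1, H2-M3, H2-Q2 and H2-T22 (Fisher's exact test, odds ratio 24.7, adjusted p = 0.00209). Among genes with a replicate 2 peak alone, the Hox family of developmental transcription factors had 7 of 39 members, among them Hoxa11, Hoxc5 and Hoxc10 (Fisher's exact test, odds ratio 35.7, adjusted p = 2.59e-06). Those 7 genes lie in clusters and share 5 peaks, so they are not 7 independent sites. Hoxd3 and Hoxd8 had a peak in replicate 1 alone (2 of 39, adjusted p = 1, Fisher's exact test), and no H2 gene had one in replicate 2 alone. Between the libraries, neither Hox (7 of 140 and 2 of 138 genes, adjusted p = 0.309) nor H2 (0 of 140 and 5 of 138, adjusted p = 0.145) passed Fisher's exact test over the 5 families compared.

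Explanations were weighed for 3 patterns. The test within the higher-scored 50% of the unshared peaks was set before its result was seen, and the other tests were chosen after. Those against evenly placed background and chance overlap draw on shares and overlaps already known, so they restate these values and add no separate evidence. The libraries analysed form 1 group, so no biological explanation was tested.

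The first pattern is that 13 interferon or antigen presentation genes had a peak in replicate 1 alone and 1, Cmpk2, in replicate 2 alone (9.42% of 138 and 0.714% of 140 genes; Fisher's exact test between libraries, unadjusted p = 0.000697). That test pools both lists and counts genes, and neighbours such as Dtx3l and Parp9 share a peak, so the 13 genes are not 13 independent sites. Background calls spread evenly over genes in replicate 1 would hold such genes as often as the genome does, but their odds ratio was 47.9 (Fisher's exact test, p = 5.73e-17). That test uses the same 13 genes that define the pattern, so it restates the excess seen above and is not separate evidence. Background that favours some promoters or multigene families such as H2 need not be even, so this test cannot exclude it. At these genes, replicate 1 peaks also called in replicate 2 had a median summit value of 51.5 and those it missed 28, a difference of 23.5 (permutation test, p = 0.0008). Shared peaks were higher over the whole replicate 1 list as well (57 against 21), so this difference does not decide whether replicate 2 was less sensitive. Depth, calling threshold and a real difference between the preparations stay open, because neither depths nor inputs were analysed here.

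The second pattern is the gene-end share of unshared peaks, 46.2% in replicate 2 and 20.9% in replicate 1. Adjacent calls count as separate peaks in these shares, and what merging them would change was not tested. Background placed evenly along the chromosomes is argued against for replicate 1, since its 20.9% exceeded each of 1000 random placements (highest 6.15%). Those placements ignore open chromatin, so background that favours gene ends stays open for replicate 1 too. Weak replicate 1 calls are argued against as the whole account. In the higher-scored 50% of the unshared peaks, 46.7% in replicate 2 and 24.7% in replicate 1 were at gene ends (odds ratio 2.68, Fisher's exact test, p = 0.000469). The replicate 1 share was 24.7% there and 20.9% in all its unshared peaks, so a partial effect of weak calls is not excluded. Members of the interferon and antigen presentation lists (69 genes) do not make up the replicate 2 set, as they were 0.714% of its genes. Other possible IRF2 targets were not counted, since no motif search was run. Non-specific recovery of promoter chromatin in replicate 2 may account for the share and remains untested without the inputs and the sequence.

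The third pattern is the 28 shared regions farther than 5000 bp from a gene end. Chance overlap is argued against, since 29 such replicate 1 peaks overlapped a replicate 2 peak and random placement gave at most 2. Regions of high coverage in any library were predicted to be taller than gene-end regions in both lists. They need not be taller, so a comparison of summit values cannot decide this. The median of the 28 far regions exceeded that of gene-end regions by 4.5 in replicate 1 (62.5 against 58, permutation test, adjusted p = 0.902) and was lower in replicate 2 (15 against 20, permutation test, adjusted p = 0.121). These tests leave distal binding sites and regions of high coverage open, and they cannot be told apart without the inputs or a repeat annotation.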
